A study of Oryza sativa with 8 samples.

How the data were processed

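Chromatin from young rice inflorescence meristems was fixed with 1% formaldehyde for 10 minutes, sonicated and immunoprecipitated with an antibody against GFP, per the labels' protocols. The labels give 4 ChIP and 4 input samples. They number the antibody of replicates 1 to 4 in sequence (ab290, ab291, ab292 and ab293), so the antibody differs between replicates as labelled, and whether different products were used is not given in the sources used here. Only the 4 ChIP samples had processed files here, and the input samples entered no comparison.

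Each file is a list of peaks called on 1 replicate, without pooling. The submitters' processing notes name bcl2fastq 2.2, Bowtie 0.12.8, MACS2 1.4.2, deepTools 3.5.4 and the build IRGSP-1.0. The peak names in the deposited lists of replicates 1, 2 and 4 name Bowtie2 as the aligner, which differs from the notes, and the names in the list of replicate 3 follow another pattern and name no aligner. Whether replicate 3 was processed differently, whether the matching input served as control, and how duplicate reads were treated are not given in the sources used here. The deposited fold enrichment is the ratio of the pileup to the caller's local background at the summit, each with 1 added. The deposited −log10 p-value and −log10 q-value are the caller's own, and the lowest −log10 q was between 1.30 and 1.31 in every list, close to a q-value of 0.05. The deposited score is 10 times the −log10 q, cut to a whole number. Start, end and summit offset are in bp, and starts were raised by 1 for printing.

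The total number of reads per library is not in the lists. The pileup at each summit was recovered instead. For each peak, the whole number of fragments and the background were found whose ratio, with 1 added to each, equals the deposited fold and whose Poisson tail equals the deposited −log10 p. A whole number within 0.002 of the deposited −log10 p existed for all 7352 peaks (100%). After 0.05 was added to every −log10 p, 0.408% of the peaks still matched. A background within 0.05% of the lowest of its list was counted as the lowest. Summit pileups ranged from 3 to 806 fragments in replicate 1, 3 to 227 in replicate 2, 4 to 1259 in replicate 3 and 3 to 538 in replicate 4. These pileups are those of called peaks and do not measure the depth of a library.

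Overlap of lists was counted at 1 bp or more and set against 1000 random placements of the other list's peaks, on the same chromosome and with widths kept. Chromosomes were taken to end at the last peak of any list, 372 Mb in all. Sequence to which reads cannot be mapped was not left out. Peaks of the 4 lists were merged, and a merged region was called reproducible with peaks of at least 3 of the 4 replicates; bedtools 2.31.1 gave the same 901 regions. Peaks were ranked within their own list by the caller's fold. The regions named are the 15 found in all 4 lists with the highest mean percentile of fold. This choice of regions was fixed before the data were examined, as the part of a rule that was to name the genes at them; its other parts, for members of gene lists, could not be applied. Clusters, segments and regions on which replicates differ are named besides, after their values were seen. Clusters are chains of reproducible regions with gaps of at most 100 kb that hold more regions than the longest chain in 95% of 1000 random placements; this step, the recovered pileups, the moves by up to 50 kb, the spread of summits and the tests by chromosome and by position along it were added after the data were seen. Shares carry 95% Wilson intervals and fragment counts exact Poisson intervals, both of which cover counting error only. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

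The steps were tested on simulated data. With 200 shared sites planted among 7352 randomly placed peaks, all 200 were recovered, and 0 reproducible regions arose without them. A planted cluster of 20 regions was recovered as a chain of 20. The pileup was recovered for 500 of 500 simulated peaks, and 1 of 500 peaks simulated without a whole pileup still matched. The planted sites overlapped in at least 3 lists by construction, and the limit that defines a cluster was not applied to the planted one. Pileups were simulated with the same formula that was used to recover them. These checks therefore test the code and not how well real sites are found.

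Alternatives set before the data were examined were other numbers of replicates per region, summits within 200 bp, reciprocal overlap of 50%, a −log10 q of at least 10, lists of equal length, and each replicate left out. Planned tests of location relative to genes, of the LEAFY-type and other DNA motifs, of motifs in shared against private peaks, of fixed gene lists and of the APO2 locus were not run. They need sequence and annotation of IRGSP-1.0, and the gene table used here belongs to another assembly, so it served only for gene names.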

Results

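The genomic binding of ABERRANT PANICLE ORGANIZATION2 (APO2) was measured by chromatin immunoprecipitation and sequencing in young inflorescence meristems of rice. APO2 is a plant-specific transcription factor, the rice orthologue of LEAFY, and is listed in the gene table as LOC4336857 with the synonyms RFL and LFY. The immunoprecipitations used an antibody against GFP, the green fluorescent protein commonly fused to a protein of interest. The study holds 4 ChIP replicates and 4 input replicates. No immunoprecipitation from tissue without a GFP-tagged protein is among them. Regions shared by the replicates are therefore not thereby shown to be bound by APO2. Each ChIP replicate has its own list of called peaks, and these 4 lists are the data described here. Positions are given on chromosomes of the IRGSP-1.0 build, counted from 1, and the genes at these positions were not analysed here. Nothing in the labels says whether the replicates came from separate plants, so p-values refer to the spread and placement of peaks in these 4 libraries.

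The first question was how many sites each replicate yielded. The list of replicate 1 held 1337 peaks, that of replicate 2 held 626, that of replicate 3 held 3308 and that of replicate 4 held 2081, a mean of 1838 ± 1146 peaks (SD, n = 4). Peaks were short, with median widths of 380, 367, 403.5 and 437 bp in replicates 1 to 4. They covered 670 kb of sequence in replicate 1, 293 kb in replicate 2, 2106 kb in replicate 3 and 1230 kb in replicate 4. The median fold enrichment at the summit, as the authors' peak caller gave it, was 5.76, 6.47, 4.997 and 5.46, and the strongest peaks reached 88.3-, 55.6-, 145- and 105-fold. The median number of ChIP fragments at a summit, recovered from the caller's fold and p-value, was 20, 13, 22 and 17. The expected background beneath the summits had medians of 2.42, 0.895, 3.75 and 2.01 fragments. The numbers of reads per library are not known from the lists, so the lengths of the lists cannot be compared as binding at equal depth.

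The second question was whether the replicates found the same sites. They overlapped far more than randomly placed peaks. Of the 626 peaks of replicate 2, 89.1% overlapped a peak of replicate 3 (95% Wilson interval 86.5 to 91.3%), 86.9% a peak of replicate 4 (84.0 to 89.3%) and 82.4% a peak of replicate 1 (79.3 to 85.2%). Of the 1337 peaks of replicate 1, 80.4% were found in replicate 3 and 76.4% in replicate 4. The lowest share was that of replicate 3's peaks found in replicate 2, at 15.3% (14.1 to 16.5%), where the longest list was set against the shortest. Over the 12 ordered pairs the mean share was 57.1%, and the highest share that 1000 random placements gave for any pair was 3.04%. Moving each peak by up to 50 kb keeps the density of peaks over long stretches but thins out tighter crowding. It gave up to 15.2% for a pair in 200 draws, and each of the 12 pairs still exceeded all of its own draws (adjusted permutation p = 0.005, the smallest possible). All 12 pairs exceeded every placement, with a one-sided permutation p of 0.001 and a Benjamini-Hochberg adjusted p of 0.001, the smallest that 1000 placements can give. When each list was limited to its strongest 626 peaks, so that all lists were equally long, the shares lay between 57.3 and 72.7%.

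Recovery rose with the strength of a peak in every replicate. In replicate 1, 99.4% of the strongest 25% of peaks by fold overlapped a peak of some other list, against 72.8% of the weakest 25%. In replicate 2 these shares were 100% and 76.3%, in replicate 3 85.9% and 21.6%, and in replicate 4 98.5% and 62.3%. The mean difference was 37.7 ± 18.5 percentage points (SD, n = 4), and Fisher's exact test was past the threshold in each list, with adjusted p-values from 7.85e-163 in replicate 3 to 5.68e-13 in replicate 2. Across the 4 replicates the exact two-sided sign test gave p = 0.125, the smallest value that 4 pairs allow. Peaks found in a single list had median folds of 4.41, 4.47, 4.35 and 4.45 in replicates 1 to 4, while peaks in regions found in all 4 lists had median folds of 8.91, 7.23, 11.9 and 8.82.

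**Figure D1:**
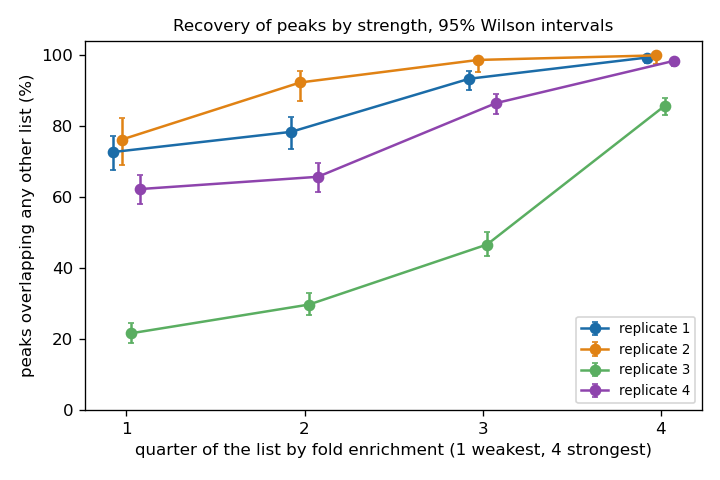
Percentage of peaks (y axis) that overlap a peak of at least 1 other replicate, for each 25% of a replicate's list ordered by fold enrichment (x axis, 1 weakest and 4 strongest), with 95% Wilson intervals; colours mark the 4 ChIP replicates. The strongest 25% are recovered at 85.9 to 100%, and the weakest at 21.6 to 76.3%, with replicate 3 lowest at each of the 4 steps.

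The third question was which sites can be called reproducible. Merging the 4 lists gave 4076 regions. Of these, 450 held a peak of all 4 replicates, 451 of 3, 698 of 2 and 2477 of a single replicate. The 901 regions with peaks of at least 3 replicates were taken as reproducible. Random placement of all 4 lists gave 0.523 such regions on average and 4 at most in 1000 placements (one-sided permutation p = 0.001, the smallest possible). Moving each peak by up to 50 kb, which keeps the density of peaks over long stretches but not tighter crowding, gave 63.1 on average and 84 at most. The reproducible regions had a median length of 773 bp and covered 1104 kb. They took up 87.5% of the peaks of replicate 2 (84.7 to 89.9%), 72.9% of replicate 1 (70.5 to 75.2%), 50.02% of replicate 4 (47.9 to 52.2%) and 27.1% of replicate 3 (25.6 to 28.6%). In replicate 3, 1787 peaks, 54.0% of its list, were found in no other replicate. Of all peaks of replicate 3, 199 lay in 5 segments of chromosomes 3, 4 and 11 where its private peaks crowded. In these segments 62.8% of its peaks had the lowest background of the list, within 0.05%, and outside them 1598 peaks (51.4%) were still private to replicate 3. Regions shared by replicates 1, 3 and 4 without replicate 2 numbered 408, and no other set of 3 replicates alone shared more than 28. The count rests on the rule: 1599 regions had at least 2 replicates and 450 had all 4. With 1 replicate left out and a peak required in all 3 others, the count was 478 regions without replicate 1, 858 without replicate 2, 473 without replicate 3 and 459 without replicate 4.

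**Figure D2:**
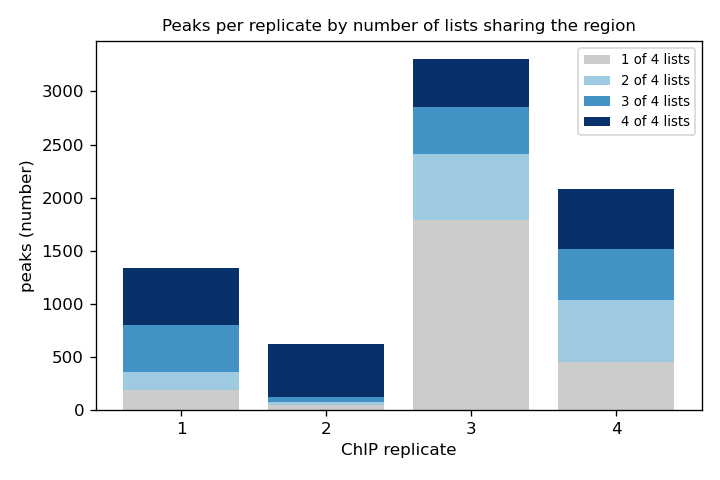
Number of peaks (y axis) in each ChIP replicate (x axis), divided by how many of the 4 lists hold a peak in the same merged region. The 1787 peaks found in replicate 3 alone form the largest block, while 80.5% of replicate 2's peaks lie in regions shared by all 4 lists.

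Summits lay close together. In the 372 regions with exactly 1 peak in each replicate, the 4 summits spanned a median of 75 bp (interquartile range 42 to 136 bp). In 65.1% of them the 4 summits lay within 100 bp. Summits drawn at random within the same peaks spanned a median of 397 bp on average over 200 draws, and 363 bp in the draw with the lowest median. The draws fell evenly over each peak, edges included. A tendency of summits to lie near the middle of a peak would by itself give part of this gap.

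The 15 regions found in all 4 lists with the highest mean percentile of fold within the lists lay on 7 chromosomes, and their mean percentiles ranged from 98.5 to 99.9. The first, on chromosome 2 from 13605229 to 13606362, was enriched 84.0-, 55.6-, 98.5- and 75.6-fold in replicates 1 to 4. Its summit held 376, 113, 797 and 297 fragments over backgrounds of 3.49, 1.05, 7.10 and 2.94, and the exact 95% Poisson interval of the 113 fragments in replicate 2 was 93.1 to 136. The second, on chromosome 12 from 24878512 to 24879811, was enriched 88.3-, 49.3-, 145- and 105-fold, the highest fold of the lists of replicates 1, 3 and 4. The third, on chromosome 7 from 23122915 to 23124204, was enriched 61.7-, 51.6-, 78.5- and 70.3-fold. On chromosome 1, the region from 40014280 to 40015807 was enriched 78.6-, 43.2-, 118- and 73.9-fold, and the region from 40289906 to 40292051 68.0-, 36.1-, 118- and 64.3-fold. The region on chromosome 3 from 29303942 to 29305549 was enriched 60.1-, 46.3-, 125- and 74.5-fold. The region on chromosome 7 from 11613916 to 11616416 was enriched 64.7-, 33.2-, 101- and 75.3-fold, and that on chromosome 11 from 16710043 to 16711735 was enriched 47.9-, 46.1-, 53.9- and 33.3-fold.

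The other 7 of these 15 regions began at 37976896, 1869854 and 8328902 on chromosome 1, at 22816973 on chromosome 3, at 27095062 on chromosome 2, at 27575876 on chromosome 6 and at 20675331 on chromosome 12. Over all 15 the lowest fold in any replicate was 21.1, in replicate 4 at the region on chromosome 12 from 20675331 to 20677946. This region lay in a dense cluster of peaks with a high background, described below, and the other 14 lay outside such clusters. The summits of the 4 replicates spanned a median of 46 bp over the 15 regions. These fold values are the caller's own and are ranked within each list only. The intervals cover counting error only, since it is not known whether duplicate reads were removed.

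**Figure D3:**
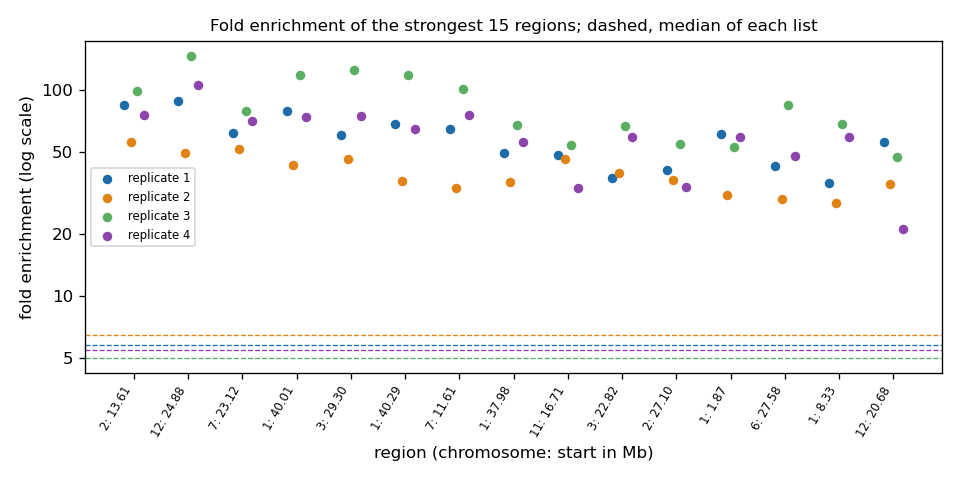
Fold enrichment at the summit (y axis, log scale) of the 15 strongest reproducible regions (x axis, chromosome and start), with 1 point per ChIP replicate and a dashed line at the median fold of each list. All points lie between 21.1 and 145, above the list medians of 4.997 to 6.47.

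Reproducible regions were spread unevenly over the genome. Along chromosome 3 there were 3.28 regions per Mb and along chromosome 1 3.61, against 0.830 on chromosome 11 and 1.55 on chromosome 7. Regions were also grouped into chains with gaps of at most 100 kb, by a rule chosen after the data were seen, and 6 chains held more than 7 regions, the length that the longest chain stayed within in 95% of 1000 random placements. Of these clusters, 4 were longer than the longest chain of any placement, which held 10 regions, and those on chromosomes 2 and 8 were not. The largest cluster lay on chromosome 12 from 20452484 to 20705437, with 32 regions and 51, 32, 55 and 80 peaks in replicates 1 to 4. The others were on chromosome 10 from 10790468 to 10920336 with 25 regions, on chromosome 4 from 9091266 to 9210356 with 20, on chromosome 1 from 33498011 to 33606313 with 18, on chromosome 2 from 14245881 to 14289462 with 10 and on chromosome 8 from 9243746 to 9284467 with 9. Together they spanned 695 kb, 0.187% of the length of the chromosomes up to the last peak of any list, and held 114 of the 901 regions (12.7%). They held 13.5, 17.4, 6.29 and 14.3% of the peaks of replicates 1 to 4. The background beneath peaks inside the clusters was 4.51 ± 0.61 times that beneath the other peaks (SD, n = 4 ratios of medians). Without the clusters, 787 reproducible regions remained. Their density still differed between chromosomes, from 0.830 to 3.28 per Mb (chi-square of 89.5 against chromosome length, permutation p = 1e-05, the smallest that 100000 draws can give, with regions treated as independent). Sequence to which reads cannot be mapped counted towards these lengths, so the differences need not come from binding.

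**Figure D4:**
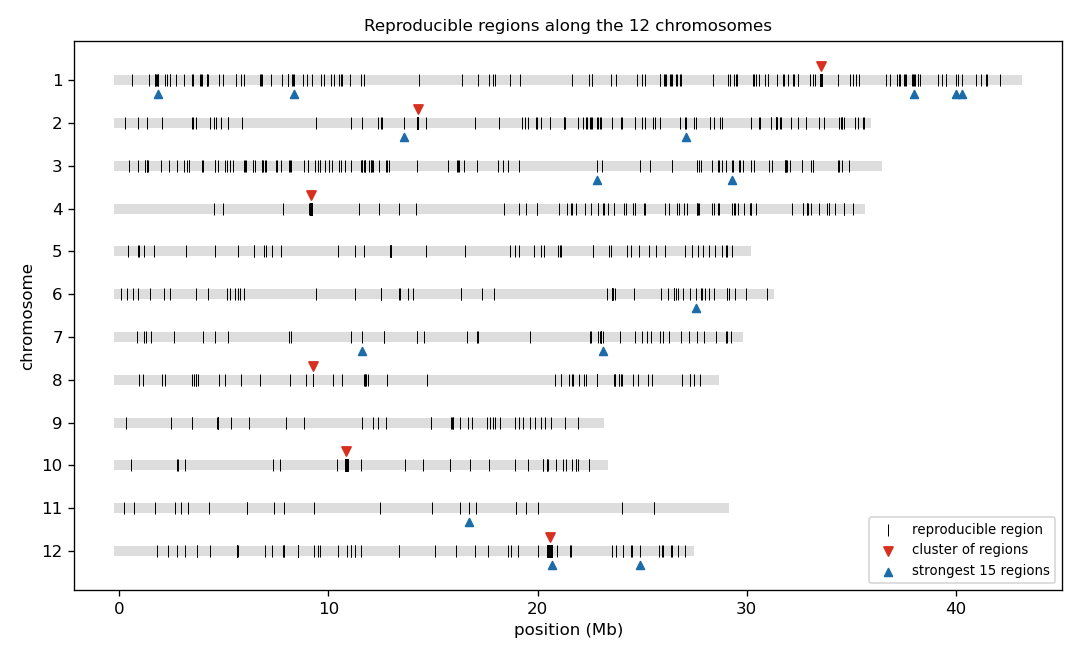
Positions (x axis, Mb) of the 901 reproducible regions (black ticks) on the 12 chromosomes (y axis), with the 6 clusters marked by red triangles above and the 15 strongest regions by blue triangles below each chromosome. The grey bars end at the last peak of any list, and chromosome 11 carries the fewest regions, at 24.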

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

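Except for the test of background in the lists of replicates 1 and 4 at replicate 3's segments and the test of the strongest peaks in the clusters, the tests in this part were chosen after the results were seen. Those exceptions were set before their own results were seen, but on segments and clusters already found in these data. Of 48 values compared across the 4 lists, 12 had 1 list far from the other 3 by Dixon's rule, which chance alone does for about 1 value in 20 when values are independent and normally distributed. Many of these values are related or bounded, so the 12 are not read as an excess over chance. The counts of peaks in segments were chosen because 1 list crowds there, so they are no independent evidence. The flagged lowest fold and number of peaks at the lowest background come wholly or largely from the same segments.

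Private peaks of replicate 3 crowded into 5 segments. On chromosome 4 from 1224464 to 1697189 it had 66 peaks and the others 0. On chromosome 11 it had 53 peaks from 4422029 to 4988321, where replicate 4 had 2, it had 20 peaks from 5211261 to 5323126, where the others had 0, and it had 36 peaks from 6591475 to 6973734, where replicate 1 had 1. On chromosome 3 from 5019592 to 5582975 it had 24 peaks, and replicates 1, 2 and 4 had 5, 5 and 9. Random placement reached chains of 20 private peaks, so the chain of 16 on chromosome 3 and that of 20 on chromosome 11 from 5211261 were within its reach, and the other 3 were not.

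Over the 5 segments, the median background of the private peaks was 0.157 times that of replicate 3's other private peaks. Of those inside, 75% lay at or below 0.560 fragments, and 75% of the others lay at or above 1.19. A longer list of weak peaks with backgrounds like the others would not by itself give this difference. Peaks of few fragments pass only over a low background, so a longer list of weak peaks is not excluded. The background of all peaks inside was 0.101 times that elsewhere, which extra copies of the segments in the ChIP DNA would not by themselves bring about. A background computed from a control does not measure copies in the ChIP DNA, so such copies are not excluded. In the 4 segments of chromosomes 4 and 11 the median summit pileup was 7 fragments, against 24 for replicate 3's other peaks. Few or no control reads are a candidate explanation, if the background was computed from a control, which is not given in the sources used here. Of the peaks inside, 62.8% had the lowest background of the list, against 0.740% elsewhere. Of the 148 peaks within 0.05% of that value (1 peak in each other list), 125 lay inside. These counts were the same at tolerances from 0.001 to 0.5%. The value is a floor whose height depends on the genome size given to the caller, so few reads and none look alike. If the background was computed from the ChIP reads instead, the floor would mean low ChIP coverage. These readings cannot be told apart here. The segment on chromosome 3 differed, with 0% of its peaks at that floor. If a control was used, this argues against missing control reads there. Its backgrounds, 1.33 times those of other private peaks and 0.901 times those of all peaks elsewhere, leave a longer list or extra copies open. Whether any control covers the segments of chromosomes 4 and 11, set apart after their backgrounds were seen, stays open, since replicates 1 and 4 had 3 peaks there, at a median background percentile of 12.7; genotype, and binding seen in replicate 3 alone, were not tested.

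Replicate 4 had 23 peaks at the start of chromosome 9, from 3710 to 37085, where the other replicates had 0. Their folds ran from 1.33, the lowest of any list against 1.88, 1.88 and 1.91 in replicates 1 to 3, to 2.39. Very deeply covered sequence may account for them, since their median background was 160 fragments, 79.9 times the median of the list. Strong local enrichment is argued against, with a median fold percentile of 0.577 within the list. No biological explanation was tested.

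The 6 clusters shared by all 4 lists coincided with a high background: the lowest of the 4 ratios of background inside to outside was 4.01. Deeply covered DNA, such as repeated or organelle-derived sequence, could therefore contribute, though the sequence itself was not analysed here. Whether the background was computed from a control is not given in the sources used here. If it was computed from the ChIP reads, dense peaks would themselves raise it. Whether these peaks passed only because coverage was deep cannot be told apart from enrichment of usual strength: the clusters held at least as large a share of the strongest 25% of peaks as of the whole list in 2 of the 4 lists, replicate 2 with 19.7% against 17.4% and replicate 3 with 10.5% against 6.29%, and a smaller share in replicates 1 (12.5% against 13.5%) and 4 (11.5% against 14.3%). No biological explanation was tested.

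On chromosome 1 from 33172635 to 33340488, replicate 4 had 8 peaks and the others 1, 2 and 2, and its chain of 6 private peaks was within the 7 that random placement reached. On chromosome 11 from 12039732 to 12177964, replicate 1 had 16 peaks and the others 1, 1 and 4, and its chain of 10 private peaks there was longer than the 6 that random placement reached. Dixon's rule also picked out the fold percentile of replicate 2 at 4 of the 15 strongest regions: 99.7 at the region on chromosome 12 from 24878512, where the other lists were at the ceiling of 100, 98.7 at that on chromosome 1 from 40289906, 98.1 at that on chromosome 7 from 11613916 and 97.4 at that on chromosome 1 from 1869854. These percentiles lie near their ceiling and come from lists of different lengths, so the gaps cannot be read as differences in binding.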

How the results depend on the processing

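The settings chosen after the data were seen were peaks moved by up to 50 kb, segments or clusters left out, 2 of 3 lists, and those for strong peaks and for clusters. The overlap between replicates stayed beyond random placement in all 12 pairs under the 6 alternatives run (adjusted permutation p = 0.005, the smallest that 200 placements can give); the mean share ranged from 39.3% with reciprocal overlap of 50% to 66.2% with lists of equal length. The higher recovery of strong peaks kept its direction in all 4 lists when peaks were ranked by −log10 p (51.3 percentage points) or matched by summits within 200 bp (50.5). The count of 901 reproducible regions depended on the rule. It was 851 with summits within 200 bp, 753 with reciprocal overlap, 1599 with at least 2 lists, and 450 with all 4 lists, with a −log10 q of at least 10 and with the strongest 626 peaks per list. These 3 equal counts are different sets: 348 of the regions at the stricter q and 369 of those from the strongest peaks overlapped the regions found in all 4 lists. With 1 replicate left out the count ranged from 459 without replicate 4 to 858 without replicate 2, since a peak was then needed in all 3 lists. With 2 of the 3 lists needed, it ranged from 1021 without replicate 3 to 1572 without replicate 2, with 1424 without replicate 1 and 1029 without replicate 4. Leaving out the crowded segments private to 1 list gave 895, and leaving out the clusters gave 787. The number of clusters, 6, ranged from 4 with gaps of 200 kb to 9 with gaps of 50 kb, and was 5 or 6 with 1 replicate left out. The 15 strongest regions were found in all 4 lists under the stricter q and in lists of equal length. Their mean percentiles moved by more than the spread between lists for 14 of the 15 under the stricter q and for 8 in lists of equal length, and the lowest were 96.3 and 95.9; shorter lists lower a percentile by construction. What depth limits was not measured, since the lists hold no library totals. No paired analysis was possible because the input samples that share the ChIP replicate numbers have no values in the files used here.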

Other observations

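The observations here were made after the data were seen. Reproducible regions outside the clusters lay more often towards the ends of the chromosomes. Of the 787, 491 (62.4%, exact 95% interval 58.9 to 65.8%) fell in the outer 25% at either end, against 50% for even placement (exact two-sided binomial test, p = 3.64e-12, with regions treated as independent). The share was above 50% on 11 of the 12 chromosomes, highest on chromosome 6 with 76.3% of 59 regions, and was 50% on chromosome 11, where 12 of 24 regions lay there. In the 4 lists taken singly, 61.4 ± 2.4% of the peaks outside the clusters lay in these outer parts (SD, n = 4). The crowded segments private to replicate 3 and the peaks of replicate 4 at the start of chromosome 9 lay there and were not left out. Replicate 3 had the highest share, 64.8%.

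Outside the clusters, 140 of the 787 regions (17.8%) had another reproducible region within 10 kb. Random placement on the same chromosomes gave 35.7 on average and 64 at most in 1000 placements (one-sided permutation p = 0.001, the smallest possible). Neither this placement nor the test of chromosome ends left out sequence to which reads cannot be mapped. Both results therefore need not come from binding.

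The lowest background in the list of replicate 3 was 0.401 fragments, and the median background of its peaks was 9.34 times that value. The height of such a floor depends on the genome size and read total given to the caller, which are not given in the sources used here.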
